A study of Mus musculus with 8 samples.

How the data were processed

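The series holds 8 Drop-seq libraries of whole mouse testis, SCARKO and WT at 4 time points. Per the labels' protocols, a WIN compound was given by mouth from 2 to 8 dpp at about 100 mg per kg per day, RA was injected at 9 dpp at 100 µg per animal, and testes were taken 8, 13 and 16 days later, at 17, 22 and 25 dpp. The 21 dpp males were untreated. The files hold raw UMI counts per gene and barcode as deposited by the authors, with whole numbers in every cell. Per the submitters' processing notes, STAR 2.5.2b, Picard 2.6.0, SAMtools 1.2 and the GRCm38 genome were used. The rule by which barcodes were chosen is not given in the sources used here. Each file held a round number of barcodes, 2500 in the WT libraries and 3000 to 5000 in the SCARKO libraries, 26500 in all.

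Groups came from the sample titles. The title of the WT library at 21 dpp also holds the word mutant and was read as WT. The titles carry no replicate numbers, and nothing says that libraries came from separate animals or days. The p-values therefore measure how far the genotype difference varies between time-matched pairs. That variation can hold technical differences and effects of genotype that change with age or synchronization. Cells with under 500 detected genes (2586 barcodes) or over 10% mitochondrial UMIs (392 barcodes) were left out, which kept 23522. Doublets were called per library with the Scrublet method of scanpy 1.11.5 at an expected rate of 5%, and the 420 called cells (1.79%) were removed. The caller marked under 0.5% of cells in 3 SCARKO libraries (0.343% at 8 dpRA, 0.201% at 16 dpRA and 0.0645% at 21 dpp) and up to 5.46% in WT at 16 dpRA, so it did not work in those 3 libraries, and doublets remain there.

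Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes and 30 principal components were taken, and cells were clustered over 15 neighbours with Leiden (leidenalg 0.10.2, resolution 1.0, seed 1) without batch integration, under Python 3.11.15. Each marker's log2 CPM (10 CPM added) was centred on its mean over clusters and divided by its SD over clusters. The score of a marker list was the mean of these values over its markers. A cluster took the name of the list with the highest score. That score had to be at least 0.75 and lead the next by 0.3, and at least 3 markers had to have 50 CPM. A cluster stayed unnamed, too, when its 10 leading genes held more markers of another class, or when it had few UMIs and no own marker among those genes. These limits were set after the data were seen, and the markers before. The names are like-names from markers, not the authors' annotation. The clusters left unnamed held 274 cells (led by genes of dividing cells such as Mki67) and 132 cells (led by long noncoding RNAs and Neat1). Of the 37113 gene symbols in the files, 34045 matched GENCODE vM21 symbols of GRCm38, with 97.1% of UMIs. Those gave chromosomes and coordinates.

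For each class, raw counts were summed per library, and genotype was tested over pairs with time point as a block, by edgeR 4.0.16 (glmQLFit and glmQLFTest, TMM, filterByExpr) in R 4.3.3, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. A pair entered when both libraries held at least 20 cells of the class, and at least 3 pairs were needed. Sertoli-like and endothelial-like cells had 3 pairs. Pachytene-diplotene, spermatid-like and peritubular myoid-like cells had too few, and there the within-pair values carry Poisson intervals for counting error only. Fold changes are SCARKO minus WT. Levels are CPM of all UMIs of the class. The library level of a gene is its CPM over all kept cells, and a class below it can hold RNA freed from other cells. The 17 gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and, as an alternative, an estimated one, adjusted over lists within a class. The lists were reported androgen-responsive Sertoli genes, blood-testis barrier and junctions, immature Sertoli, mature Sertoli secretory and hormone, retinoid handling, steroidogenesis, cholesterol synthesis, spermatogonial, double-strand break formation, synaptonemal complex and cohesin, meiotic recombination and crossover, meiotic division competence, pachytene piRNA pathway, testis-specific energy metabolism, acrosome and spermatid, p53 and apoptosis, and immediate early and dissociation stress. The androgen-responsive list came from general knowledge of published work, which may include this study, so its direction is not independent evidence.

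Shares were compared by exact two-sided sign-flip permutation tests over pairs, with Clopper-Pearson 95% intervals per library. X shares had Wilson score 95% intervals. A count of 0 was given the limit of 3 counts. Intervals and limits cover counting error only. For the 13 dpRA pachytene-diplotene pair, list medians of log2 ratios (10 CPM added, genes with at least 20 UMIs) were ranked among 10000 random lists of the same size matched on expression.

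Before the data were examined, the groups, tests, lists, markers and alternatives were fixed, as was the rule for named genes. It took list members past the threshold, the 10 largest rises and falls per class past the threshold with 1 sign in each pair and a mean of at least 50 CPM, and Ar with the androgen-responsive genes always. Where fewer than 5 genes passed, it took up to 10 genes per direction with a log2 ratio of at least 1 in each pair and at least 30 UMIs, which gave none in early prophase and endothelial-like cells. Mitochondrial, ribosomal protein, Y-linked and symbol-less genes stayed out of the ranked parts. The alternatives were DESeq2 1.42.0 size factors and Wald test, no low-count filter, no time block, leaving out each pair, 300 or 1000 detected genes, doublets kept, Leiden resolution 0.5 or 2.0 and unpaired permutation. Added after seeing the data were a removal of the 5% highest doublet scores, a fit of genes at or above the library level only, and a fit of each class on the cells of its largest cluster only, where 3 pairs kept at least 20 cells, with gene lists tested there at the preset and at an estimated correlation.

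The tests were also tried on simulated counts with 200 genes set to change 2-fold or 4-fold, a check written after the first fits of the real counts. Of the changed genes tested, in simulated Sertoli-like cells (8171 genes) 54.9% of the 2-fold and 93.4% of the 4-fold changes were recovered. For spermatogonia-like cells these shares were 43.8% and 92.9%, for early prophase cells 37.5% and 97.6%, for Leydig-like cells 60.8% and 92.3%, for mesenchymal-like cells 66.0% and 100%, for endothelial-like cells 46.5% and 100%, and for macrophage-like cells 50.0% and 97.8%. In the sum over all kept cells 0% of either were recovered (17694 genes), so that test could not call such changes. In the 7 classes with calls, 2.17% to 9.49% of calls were false. With no gene changed, 1 call was made for Sertoli-like cells and 0 elsewhere. Each gene was drawn independently with its fitted spread, so shifts shared by many genes of a library were not simulated. The false-call rates do not cover such shifts.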

Results

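Dissociated cells of whole mouse testes were profiled by Drop-seq, in which a cell and a barcoded bead share a droplet and the 3′ ends of its transcripts are counted as unique molecular identifiers (UMIs). By their labels, SCARKO males carried a floxed androgen receptor gene, Ar, and an Amh-driven Cre meant to delete it in Sertoli cells, the somatic cells that nurse germ cells inside the seminiferous tubule. WT males were littermates without Cre. In 6 libraries the first wave of spermatogenesis had been synchronized with a WIN compound that blocks retinoic acid synthesis, followed by an injection of retinoic acid (RA), and testes were taken 8, 13 and 16 days past RA (dpRA). The other 2 libraries came from untreated males 21 days post-partum (dpp). Each genotype had 1 library per time point, so a genotype difference could be set only against the spread between the 4 time-matched pairs, and the labels do not say how many animals a library holds. Total counts per library ran from 8795178 UMIs (SCARKO, 21 dpp) to 16446375 UMIs (WT, 16 dpRA), and 23102 cells were kept, with a median of 2299 UMIs in SCARKO and 2662 UMIs in WT cells. The question behind the design was how androgen action on Sertoli cells bears on the passage of germ cells through meiosis.

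The kept cells fell into 29 clusters, of which 27 received the name of 1 of 11 cell classes from fixed markers and 2 stayed unnamed. Leydig-like cells, the androgen-producing cells of the interstitium, were numerous in each library, from 519 (WT, 21 dpp) to 2238 cells (SCARKO, 16 dpRA). Sertoli-like cells ranged from 15 (WT, 16 dpRA) to 638 (SCARKO, 8 dpRA). Germ cells numbered 3548 in all, from 81 (WT, 8 dpRA) to 1410 (WT, 21 dpp), and were divided into spermatogonia-like, early prophase spermatocyte-like (preleptotene to zygotene), pachytene-diplotene spermatocyte-like and spermatid-like cells. The number of barcodes in the files was a round number between 2500 and 5000 per library, so shares below are shares of the deposited barcodes that passed the filters and not of the cells of a testis.

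Pachytene-diplotene spermatocyte-like cells include pachytene, the stage at which homologous chromosomes are fully paired. They formed 65.6% of the germ cells in the WT library at 16 dpRA (602 of 917 cells, exact 95% interval 62.5 to 68.7%). In the SCARKO library they formed 2.98% (9 of 302, 1.37 to 5.58%). At 21 dpp they formed 63.0% in WT (889 of 1410, 60.5 to 65.6%) and 4.26% in SCARKO (11 of 258, 2.15 to 7.50%). The gap was smaller at 13 dpRA, with 48.0% in WT (143 of 298, 42.2 to 53.8%) and 24.8% in SCARKO (36 of 145, 18.0 to 32.7%). At 8 dpRA the WT library held 0 of 81 germ cells of this class, which allows a share of up to 3.70% by the limit of 3 counts (exact 95% upper bound 4.45%), and the SCARKO library 1 of 137. Spermatid-like cells were found in WT at 16 dpRA (130 of 917, 14.2%, 12 to 16.6%), at 21 dpp (56 of 1410, 3.97%, 3.01 to 5.13%) and as 1 cell at 13 dpRA. The WT count at 21 dpp depended on the clustering. There 72 of the pachytene-diplotene cells joined the class at Leiden resolution 2.0, and 68 did with doublets kept. In SCARKO there were 0 of 302 at 16 dpRA and 0 of 258 at 21 dpp, which allow shares of up to 0.993% and 1.16% by the limit of 3 counts (exact 95% upper bounds 1.21% and 1.42%). That 0 holds for the filter of 500 genes: with at least 1000 genes per cell, a cluster of 26 cells led by 1700101O22Rik, Tnp2 and Tnp1 was also named spermatid-like. This cluster had a median of only 2098 UMIs and a score of 1.96, with macrophage next at 1.13. It held 17 SCARKO cells at 16 dpRA and 1 each at 13 dpRA and 21 dpp, all in unnamed clusters at 500 genes, and 7 WT cells. The cluster led by Prm2 and Prm1, with a median of 10928 UMIs and a score of 4.43, still held WT cells only. The SCARKO mean was then 2.02% against 5.70% in WT, lower in 2 pairs and higher in 1 (exact sign-flip permutation p = 0.5).

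The earlier stages took the larger share of SCARKO germ cells at 16 dpRA and 21 dpp. Spermatogonia-like cells formed 51.0% of SCARKO (45.2 to 56.8%) and 3.71% of WT germ cells (2.58 to 5.14%) at 16 dpRA, 66.3% against 21.2% at 21 dpp, and close to equal shares at 8 dpRA (62.8% against 63.0%) and 13 dpRA (26.9% against 25.8%). Early prophase spermatocyte-like cells formed 48.3% of SCARKO and 25.8% of WT germ cells at 13 dpRA, 46.0% against 16.5% at 16 dpRA, and 29.5% against 11.8% at 21 dpp. Germ cells as a whole made up 40.1% of the kept cells in WT and 7.58% in SCARKO at 16 dpRA, 60.3% and 8.33% at 21 dpp, and 3.79% and 4.71% at 8 dpRA. Over the 4 pairs the pachytene-diplotene share was 44.2% ± 30.5 (SD, n = 4) in WT and 8.20% ± 11.2 (SD, n = 4) in SCARKO, lower in 3 pairs and higher in 1 (exact sign-flip permutation test, two-sided, p = 0.25, adjusted over the 4 stages 0.25). The SDs of shares here and below are taken over the 4 time points, so they include change between time points. The paired difference was -36.0 points ± 30.2 (SD, n = 4). The exact p was also 0.25 for the shares of spermatogonia-like, early prophase and spermatid-like cells and of all germ cells. The smallest p this test allows with 4 pairs is 0.125, so no share could pass 0.05, and the exact binomial intervals cover counting error in single libraries only. Pachytene-diplotene cells were also deeper in WT, with a median of 10257 UMIs at 16 dpRA against 4956 in SCARKO.

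**Figure D1:**
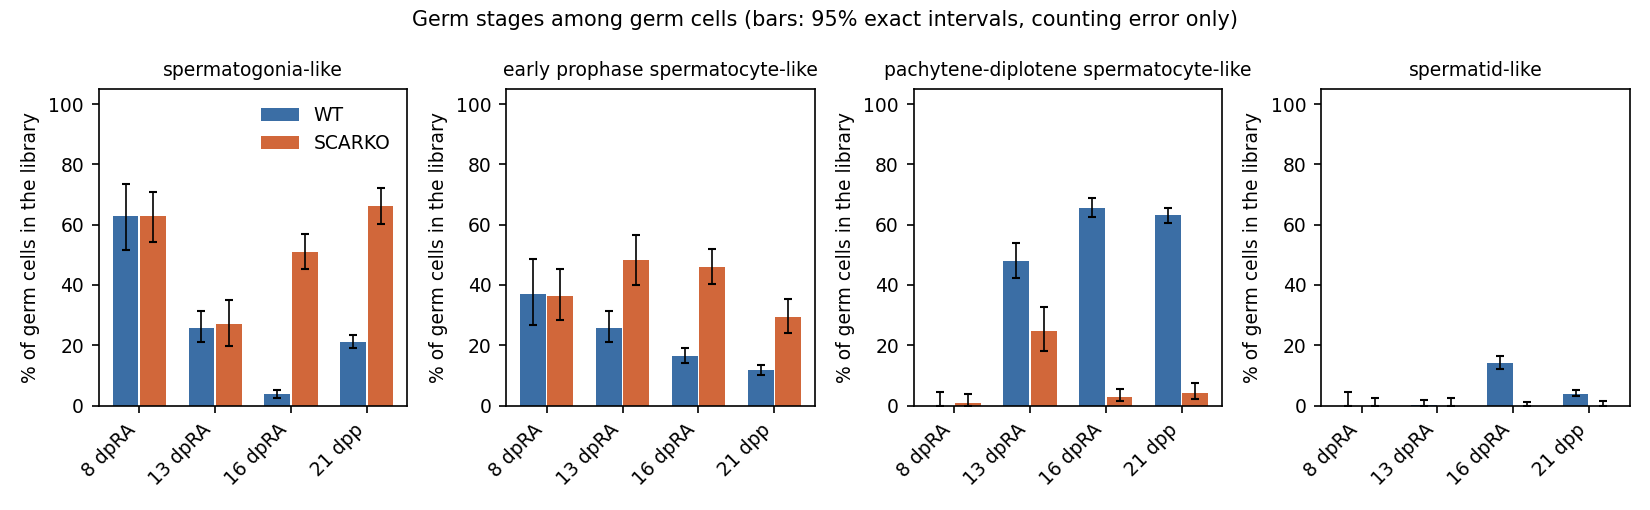
Share of germ cells in each of 4 stages (y axis, % of the germ cells of a library) by time point (x axis) in WT and SCARKO libraries, 1 library per bar, with exact 95% binomial intervals that cover counting error only. Pachytene-diplotene cells stand at 65.6% and 63.0% in WT at 16 dpRA and 21 dpp, and at 2.98% and 4.26% in SCARKO.

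Early prophase cells fell into a cluster led by Prdm9, Stra8 and Tex15, genes of meiotic entry and of the formation and repair of meiotic double-strand breaks, and a cluster led by Sycp1, Meiob and Hormad1, components of the chromosome axis, synapsis and recombination. At 8 dpRA the second cluster held 4 of 50 SCARKO and 0 of 30 WT cells. At 13 dpRA all 70 SCARKO and all 77 WT cells of the class lay in the first cluster. At 16 dpRA the second cluster held 92.1% of the WT cells (139 of 151, exact 95% interval 86.5 to 95.8%) and 64.7% of the SCARKO cells (90 of 139, 56.2 to 72.7%). At 21 dpp it held 57.2% of the WT cells (95 of 166, 49.3 to 64.9%) and 42.1% of the SCARKO cells (32 of 76, 30.9 to 54.0%), so that most SCARKO cells lay in the first and most WT cells in the second cluster. These shares compare single libraries and have no replicate check.

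Pachytene-diplotene cells could be set side by side only at 13 dpRA, where both libraries had at least 20 of them, 36 in SCARKO and 143 in WT. Summed UMIs weigh deep cells more. A cluster with a median of 28940 UMIs held 11 of the SCARKO and 49 of the WT cells. The class medians were 3387 UMIs in SCARKO and 4043 UMIs in WT, so the values below lean on those deep cells. Genes of meiotic recombination and crossover stood higher in SCARKO, with a median log2 ratio of 0.41 over 15 members, 11 higher and 4 lower, at percentile 99.96 of 10000 random lists matched on expression. Among them Tex15 had the lowest log2 ratio, -1.32 on 2 and 24 UMIs (ratio interval 0.0459 to 1.61), and Spata22 stood at 59.7 CPM (counts scaled to all UMIs of the class) in SCARKO and 29.9 CPM in WT, with a Poisson 95% interval of the ratio of 1.16 to 3.34. Genes of testis-specific energy metabolism stood lower, with a median of -0.26 over 9 members at percentile 1.72: the lactate dehydrogenase Ldhc measured 4271 CPM in SCARKO and 5650 CPM in WT, a log2 ratio of -0.40, and the phosphoglycerate mutase Pgam2 had a log2 ratio of -0.49. The synaptonemal complex list had a median of 0.16 (percentile 94.8), with Sycp1 1.53 times as high in SCARKO (1.35 to 1.73). The median was -0.06 for meiotic division competence (percentile 32.2) and -0.05 for the pachytene piRNA pathway (percentile 34.6), where Mael had a log2 ratio of -0.42. Lists of Sertoli-cell genes had a median of 0.34 for mature Sertoli secretory genes (percentile 98.8) and -0.47 for androgen-responsive genes (percentile 2.46). The immediate early and dissociation stress list, a sign of cell handling, had a median of 0.33 (percentile 98.0). The percentiles describe these 2 libraries, with no test of genotype.

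The targeted gene was measured first. Ar (chromosome X, 98148769 to 98323215, GRCm38) stood at 16.6 CPM in SCARKO and 115 CPM in WT Sertoli-like cells at 8 dpRA, at 53.6 and 60 CPM at 13 dpRA, and at 28.1 and 173 CPM at 21 dpp. At 16 dpRA Ar had 0 of 205771 UMIs in SCARKO, which allows up to 14.6 CPM, and 3 UMIs (117 CPM) in the 15 WT cells. Over the 8 dpRA, 13 dpRA and 21 dpp pairs Ar fell by 2.07 on the log2 scale (SE 0.38, edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 0.00595). At 13 dpRA the SCARKO over WT ratio of Ar had an interval of 0.435 to 1.94, so no difference was detectable at that depth. In Leydig-like cells, where the gene was not targeted, Ar ranged from 68.2 to 121 CPM over the 8 libraries. The labels do not say which exons are floxed, and a 3′ tag outside the deleted part checks nothing about the deletion, so these values are not a test of the labels.

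Genes reported to respond to androgen in Sertoli cells were lower in SCARKO. Of the 8 members tested, 6 fell and 0 rose (7 fell adjusted over the list alone). Rhox5, an X-linked homeobox gene, fell by 3.87 on the log2 scale (SE 0.62, adjusted p = 0.00212), and the dopamine receptor gene Drd4 fell by 3.58 (SE 0.45, adjusted p = 0.00040). Tsx fell by 2.16 (SE 0.26), Gpd1, a glycerol-3-phosphate dehydrogenase, by 2.03 (SE 0.40), the epididymal and Sertoli protease inhibitor gene Eppin by 1.96 (SE 0.21) and Susd3 by 1.91 (SE 0.24), each with an edgeR adjusted p of at most 0.0103. Tubb3 had a log2 change of -0.62 (SE 0.21, adjusted p = 0.135) and Ldlr, the LDL receptor gene, of 0.84 (SE 0.45, adjusted p = 0.386), neither of which passed. Fhod3, Corin and Cldn3 had too few counts to be tested.

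The size of these differences varied between pairs. Rhox5 had 0 UMIs in SCARKO and 106 UMIs (122 CPM) in WT Sertoli-like cells at 8 dpRA, at least 65.9-fold lower against a floor of 3 UMIs (95% upper bound of the ratio 0.0190), and 0 against 61 UMIs (229 CPM) at 21 dpp, at least 48.8-fold lower (upper bound 0.0260). At 13 dpRA it stood at 90.7 CPM in SCARKO (44 UMIs) and 330 CPM in WT (66 UMIs), a log2 ratio of -1.86. Drd4 had log2 ratios of -4.99 at 8 dpRA, -1.82 at 13 dpRA and -5.37 at 21 dpp, and Tsx of -2.99, -1.29 and -2.25. Corin, a transmembrane protease gene, had 0 against 22 UMIs at 8 dpRA (at least 13.7-fold lower, upper bound of the ratio 0.0979), 7 against 2 UMIs at 13 dpRA (ratio interval 0.275 to 14.2) and 0 against 22 UMIs at 21 dpp (at least 17.6-fold lower, upper bound 0.0760). Fhod3 was higher in SCARKO at 8 dpRA, with 39 UMIs against 1 (ratio interval 3.54 to 847). The floors count 3 UMIs per library and leave out the counting error of the WT value, which the upper bounds include, and the difference between time points was not tested. The 16 dpRA pair, with 15 WT Sertoli-like cells, did not enter the test.

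**Figure D2:**
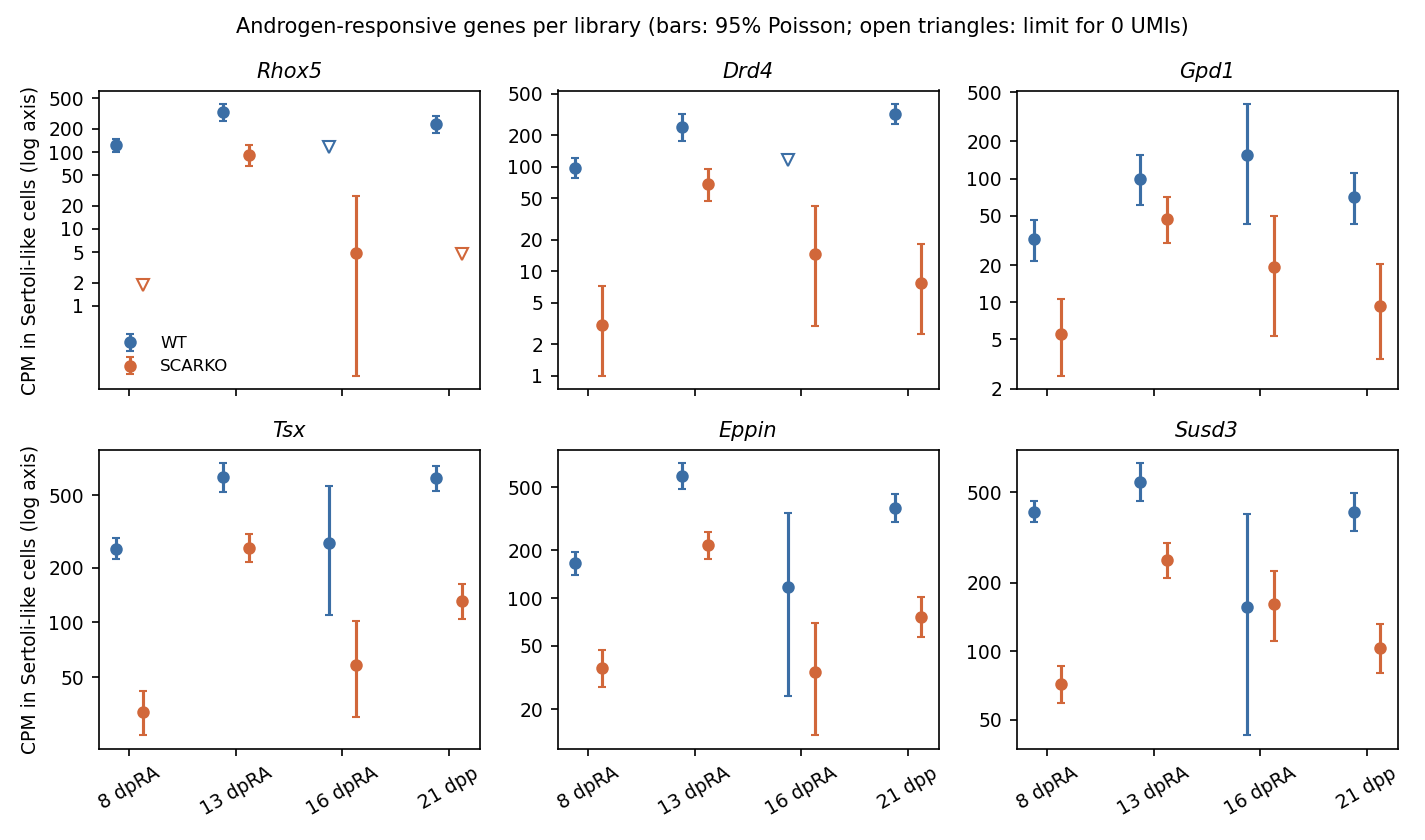
CPM (y axis, log scale) of 6 androgen-responsive genes in Sertoli-like cells by time point (x axis), 1 library per point, with 95% Poisson intervals and open triangles at the limit that 0 UMIs allow. Rhox5 lies at 90.7 CPM in SCARKO at 13 dpRA and at the limit for 0 UMIs at 8 dpRA and 21 dpp.

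Across all genes, 91 rose and 162 fell in SCARKO Sertoli-like cells out of 8520 tested. Besides Rhox5 and Drd4, the largest falls that held in each of the 3 pairs were those of the beta-defensin Defb45 (log2 change -3.11, SE 0.29), the X-linked genes Gja6, a connexin, (-2.89, SE 0.42) and Gm648 (-2.62, SE 0.37), the membrane glycoprotein gene Emb (-2.43, SE 0.23) and Bend4 (-2.27, SE 0.35). Smim24 (-2.37), Ldhal6b (-2.28) and Sept12 (-2.27) also fell, but their level in Sertoli-like cells was only 0.365, 0.340 and 0.320 times their level in the whole library. The largest rises were those of Oxct1, an enzyme of ketone body use, (2.04, SE 0.23), Bcan (1.86, SE 0.26), Filip1l (1.85, SE 0.37), the cyclin D1 gene Ccnd1 (1.81, SE 0.42), Cxxc5 (1.80, SE 0.26), Phldb2 (1.78, SE 0.37), the cytokine signalling suppressor Socs2 (1.67, SE 0.34), Gstm2-ps1 (1.67, SE 0.33), 4930486L24Rik (1.61, SE 0.34) and the TWEAK receptor gene Tnfrsf12a (1.54, SE 0.28). Gstm2-ps1 is annotated as a processed pseudogene and is uncertain where reads are shared with its parent gene, and Bcan is also among the leading genes of 1 of the 3 Sertoli-like clusters. All of these had an edgeR quasi-likelihood adjusted p of at most 0.0270. Some rises rest on few WT UMIs, with 1 each for Filip1l and Phldb2 at 21 dpp and 1 for Socs2 at 13 dpRA. At 16 dpRA, outside the test and with 15 WT cells, the signs of the rises were mixed. There Filip1l was lower in SCARKO (log2 ratio -2.01, ratio interval 0.0862 to 0.806) and Tnfrsf12a higher (1.51, 1.08 to 10.7).

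The Sertoli-like class was spread differently over its 3 clusters. At 21 dpp the largest (cluster 7, led by Shbg and Cst9) held 139 of 145 WT and 175 of 331 SCARKO cells, at 8 dpRA 115 of 178 and 323 of 638, and at 13 dpRA 53 of 75 and 127 of 225. Within cluster 7, a fit added after the results were seen, 30 genes rose and 62 fell of 6700 tested, and 88 of these 92 were also called in the whole class. Rhox5 (-3.42), Drd4 (-3.33), Tsx (-2.21), Eppin (-1.90) and Susd3 (-1.75) fell there too, as did Jam3 (-1.20) and Cdkn1a (-2.62), while Oxct1 (1.94), Bcan (2.65), Rbp1 (1.19) and Jun (1.74) rose. Ar (-1.76, adjusted p = 0.106), Gpd1 (-1.85, adjusted p = 0.0834), Espn (-0.64, adjusted p = 0.161), Gja1 (-0.40, adjusted p = 0.391) and Aldh1a2 (0.76, adjusted p = 0.220) did not pass by edgeR with Benjamini-Hochberg adjustment in that cluster. Neither did Socs2 (1.54, adjusted p = 0.139), Cyp26b1 (1.22, 0.126), Id4 (-1.06, 0.122), Insl3 (1.18, 0.142), Sycp2 (-1.13, 0.109), Tdrd1 (-1.80, 0.0642), Mybl1 (-1.21, 0.0559) and Slc2a3 (-2.17, 0.0559), all called in the whole class.

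Of 14 junction genes of the blood-testis barrier, 3 fell and 0 rose: the adhesion molecule Jam3 (-1.43, SE 0.22), the actin bundler Espn (-0.87, SE 0.20) and the connexin Gja1 (-0.74, SE 0.19). Of 9 genes of retinoid handling, 3 rose and 0 fell: the retinol-binding protein Rbp1 (1.14, SE 0.25), the retinoic acid synthesizing Aldh1a2 (0.88, SE 0.21) and the retinoic acid degrading Cyp26b1 (1.30, SE 0.34), the last at 0.287 times its library level. At 16 dpRA, outside the test, Rbp1 was lower in SCARKO (log2 ratio -1.10, ratio interval 0.343 to 0.648), while Cyp26b1 had 9 UMIs against 0 in WT. Of 6 p53 and apoptosis genes, the cyclin-dependent kinase inhibitor Cdkn1a fell (-2.05, SE 0.28). Of 11 immediate early and dissociation stress genes, Jun rose (1.12, SE 0.25). Of 5 spermatogonial genes Id4 fell (-1.15, SE 0.27), of 11 steroidogenesis genes the Leydig hormone Insl3 rose (1.24, SE 0.27), and of 14 cholesterol synthesis genes Fdps rose (1.69, SE 0.41), the latter pair at 0.0527 and 0.140 times their library level. None of 12 mature Sertoli secretory genes, 3 immature Sertoli genes, 11 meiotic division genes or 6 recombination genes passed, nor did the 1 double-strand break gene and the 1 acrosome gene tested. Some genes known from germ cells also fell: 4 of 6 in energy metabolism, with Ldhc at -2.26 (SE 0.32) and Pgam2 at -2.38 (SE 0.44), 3 of 10 in the piRNA pathway, with Piwil1 at -2.31 (SE 0.35), Tdrd1 and Mybl1, and Sycp2 among 10 synaptonemal genes. Ldhc, Pgam2, Piwil1 and Sycp2 stood at 0.304, 0.274, 0.389 and 0.406 times their library level, but Tdrd1 at 0.937 and Mybl1 at 1.71 times. Tdrd1 and Mybl1 were also lower at 8 dpRA, with log2 ratios of -1.52 and -1.27.

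By camera with a preset correlation, the androgen-responsive list was lower than other genes in Sertoli-like cells (adjusted p = 2.1e-06; adjusted p = 0.591 with an estimated correlation). With the preset correlation the lists of energy metabolism (adjusted p = 0.00159), meiotic division (0.00159), piRNA pathway (0.00446) and mature Sertoli secretory genes (0.00874) were also lower, and those of cholesterol synthesis (0.00358) and steroidogenesis (0.00696) higher. With an estimated correlation each of these lists had an adjusted p of 0.591 or 0.627, and no list in any class passed 0.05. Without the 8 dpRA pair 476 genes were called in Sertoli-like cells, without the 13 dpRA pair 106 and without the 21 dpp pair 54. DESeq2 called 74 genes, and 1 gene was called without the time point as a block.

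In spermatogonia-like cells, 16 of 9325 genes fell and 0 rose (568 at an unadjusted p under 0.05; DESeq2 called 18). Those lower in each pair at a mean of at least 50 CPM were Cetn1 (log2 change -3.18, SE 0.41), Spink2 (-3.14, SE 0.32), Fabp9 (-3.14, SE 0.30), Ldhc (-3.13, SE 0.29), AA467197 (-2.67, SE 0.34), Fam229b (-2.35, SE 0.29) and Phkg2 (-1.31, SE 0.19), most of them known from later spermatogenic cells. Each of the 16 stood below its library level, at a median of 0.170 times that level. Of 14 spermatogonial genes, 14 synaptonemal genes, 15 recombination genes and 4 double-strand break genes, 0 passed. Of 5 energy metabolism genes, Ldhc and Ldhal6b fell (4 fell adjusted over the list alone). In early prophase cells 3 of 4738 genes fell, Spink2 (-2.79, SE 0.39), Crisp2 (-2.94, SE 0.45) and Ggnbp1 (-2.75, SE 0.43), named after their values were seen, and 0 rose (381 at an unadjusted p under 0.05; DESeq2 called 6). All 3 lay below their library level. The recombination list was lower by camera with a preset correlation (median -0.44, 0 of 17 members passing, adjusted p = 5.4e-05; adjusted p = 0.257 with an estimated correlation). Within the Prdm9 cluster alone (8 dpRA, 13 dpRA and 21 dpp pairs, 11 members) its adjusted p was 3.7e-08 with the preset and 0.203 with an estimated correlation. Lists of other cells moved with it in the class: the spermatogonial list had a median of 1.04 (3 of 3 higher adjusted over the list alone), the mature Sertoli list 0.98 (4 of 7) and the steroidogenesis list 0.95 (3 of 8). Among genes at or above their library level 0 were called in either class (227 and 116 at an unadjusted p under 0.05), while without the 8 dpRA pair 470 and 174 genes were called by edgeR and without the 13 dpRA pair 0 in both.

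Somatic cells outside the tubule were compared in the same way. In Leydig-like cells 21 genes rose and 213 fell of 14080 tested by the edgeR quasi-likelihood test. The rises at or above the library level included the fatty acid synthase Fasn (0.87, SE 0.16) and the defensin Defb19 (0.79, SE 0.16), and those below it Cyp26b1 (1.35, SE 0.22), Ltbp4 (1.19, SE 0.19) and the growth factor Igf1 (1.07, SE 0.16). Defb19 was among the Sertoli markers used for naming. Igf1 was among the mesenchymal markers and led a mesenchymal-like cluster. Whether these rises arose in Leydig-like cells themselves was not tested. Of 13 steroidogenesis genes 0 passed, with a median log2 change of -0.09. The largest falls were of sperm genes, among them Crisp2 (-3.54, SE 0.31), Spink2 (-3.48, SE 0.35), Dkkl1 (-3.48, SE 0.32) and Fabp9 (-3.27, SE 0.28). Of the 213 genes that fell, 212 stood below their library level, and none was called when only genes at or above it were fitted (200 at an unadjusted p under 0.05). Most Leydig-like cells of the 2 libraries at 8 dpRA lay in 1 shared cluster (94.9% in SCARKO and 89.7% in WT), while at the 3 other times the SCARKO and WT libraries each had their own main cluster (clusters 2 and 11 at 13 dpRA, 5 and 10 at 16 dpRA, 1 and 14 at 21 dpp). Within the largest cluster alone 4 of 3355 genes were called, all lower. It was the main cluster of SCARKO at 21 dpp and held few cells of some other libraries. Among these were WT at 21 dpp (37 of 519 Leydig-like cells) and SCARKO at 8 dpRA (38 of 743). Only 17 of the calls of the whole class could be tested in this cluster, and 16 kept their sign. There Cyp26b1 (-0.27, edgeR adjusted p = 0.994) and Igf1 (0.04, 0.997) were no longer higher. Ltbp4 (0.86, 0.806), Fasn (0.75, 0.806) and Defb19 (0.82, 0.0596) had positive estimates but did not pass. Without the 16 dpRA pair 0 genes were called (816 at an unadjusted p under 0.05), and without the 8 dpRA pair 907.

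In interstitial mesenchymal-like cells 114 of 10367 genes passed, and 9 of them rose. Of the rises, 5 stood above the library level: the chemokine Cxcl12 (0.73, SE 0.14), the basement membrane collagen Col15a1 (0.67, SE 0.14), the mitochondrial transhydrogenase Nnt (1.07, SE 0.19), Arhgap24 (0.81, SE 0.16) and Sned1 (0.65, SE 0.13). The class lay in clusters 0 and 4, and cluster 0 held 732 of 776 SCARKO and 230 of 334 WT cells at 16 dpRA, 503 of 579 and 69 of 107 at 21 dpp, 812 of 1211 and 348 of 657 at 13 dpRA, and 200 of 1053 and 60 of 242 at 8 dpRA. Within cluster 0 edgeR called 93 genes, with Cxcl12 (0.62, adjusted p = 0.0287) and Nnt (1.04, adjusted p = 0.00726) among them, while Col15a1 (0.61, adjusted p = 0.125), Arhgap24 (0.70, 0.108) and Sned1 (0.50, 0.165) did not pass. All 67 calls of the whole class that could be tested there kept their sign. Of 15 genes of the dissociation stress list 2 fell, Jun (-0.94, SE 0.14) at 1.93 times and Hsp90aa1 (-0.92, SE 0.16) at only 0.339 times the library level. Insl3 (1.05, SE 0.17), Hsd3b1 (1.15, SE 0.25) and Defb19 (1.02, SE 0.21) rose below their library level. Among the falls 100 lay below the library level, led by Crisp2 (-3.70, SE 0.34) and Ropn1l (-3.57, SE 0.34). Nnt, which some mouse strains carry in a mutated form, was higher in SCARKO in each of the 4 pairs, and the labels give a mixed strain background. When only genes at or above the library level were fitted, 3 rose and 7 fell by edgeR with Benjamini-Hochberg adjustment, and without the 8 dpRA pair 557 genes were called.

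In macrophage-like cells 27 genes rose and 59 fell of 7464 tested, and all 86 stood below their library level. The rises included genes of mesenchymal and Sertoli cells such as Dcn (1.62, SE 0.33), Col1a2 (1.44, SE 0.27) and Defb19 (1.5, SE 0.30), and the falls Dnah8 (-3.50, SE 0.33), Ldhc (-3.49, SE 0.30) and Dkkl1 (-3.16, SE 0.36). Of 14 cholesterol synthesis genes Hmgcs1 rose (1.35, SE 0.28; 8 rose adjusted over the list alone). The list was higher by camera with a preset correlation (median 0.95, adjusted p = 2.7e-09; adjusted p = 0.243 with an estimated correlation). Steroidogenesis genes of Leydig cells shifted as much, with a median of 0.99 and Star, Cyp11a1, Hsd3b1, Hsd3b6 and Insl3 higher adjusted over the list alone. In endothelial-like cells edgeR called 0 of 2240 genes (71 at an unadjusted p under 0.05), and DESeq2 also called 0. Restricted to genes at or above the library level, edgeR called 0 genes in macrophage-like cells (179 at an unadjusted p under 0.05). Peritubular myoid-like cells had enough cells in both libraries only at 8 dpRA and were not tested.

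In Leydig, mesenchymal, macrophage or spermatogonia-like cells 270 genes fell while standing below their library level. In the WT library at 16 dpRA 254 of them were highest in pachytene-diplotene or spermatid-like cells and 16 elsewhere, among these Hsp90aa1, Sycp3 and Acta2, and at 21 dpp 256 and 14. Together they reached 260530 CPM in WT pachytene-diplotene cells at 16 dpRA. They made up 192750 CPM of the whole WT library at 16 dpRA, and 22814 CPM of its Leydig-like, 29301 CPM of its mesenchymal-like and 35424 CPM of its macrophage-like cells. In the SCARKO library at 16 dpRA the whole held 10188 CPM, and the same 3 classes between 5954 and 7604 CPM. At 8 dpRA, where neither genotype had late germ cells in number, the whole libraries stood at 6889 CPM in SCARKO and 6632 CPM in WT. The classes did not rise in proportion to the library: their median was 88.9% of the library level in WT at 8 dpRA and 15.2% at 16 dpRA. From 16 dpRA to 21 dpp the WT library fell to 167330 CPM while its Leydig-like (24072 CPM) and mesenchymal-like cells (35501 CPM) rose. Its macrophage-like cells fell, to 33216 CPM. Within a library the highest of these 3 classes exceeded the lowest by 1.10-fold to 1.55-fold. Other classes stood higher: at 8 dpRA spermatogonia-like cells held 16145 CPM in SCARKO and 15556 CPM in WT against 4854 and 5001 CPM in Leydig-like cells, and WT myoid-like cells 13564 CPM. At 21 dpp WT Sertoli-like cells held 40170 CPM. The genes were picked by their falls in these libraries, so their lower level in SCARKO is not independent evidence.

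**Figure D3:**
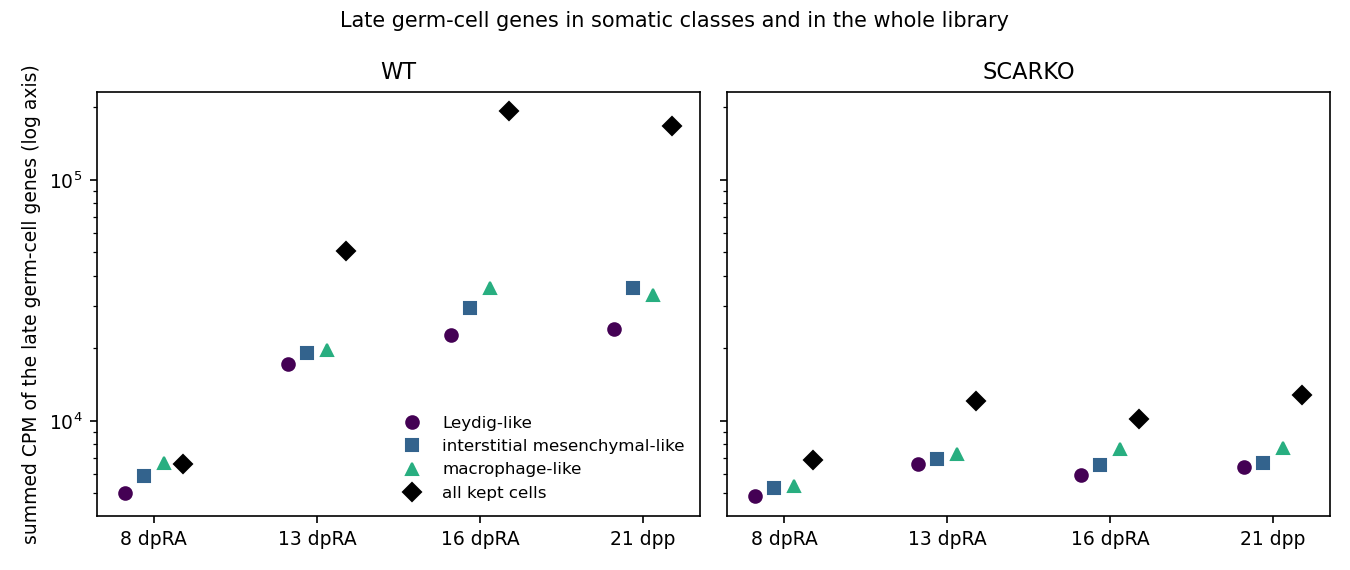
Summed CPM (y axis, log scale) of the 270 genes, most of them highest in late germ cells, by time point (x axis) in Leydig-like, interstitial mesenchymal-like and macrophage-like cells and in all kept cells, WT on the left and SCARKO on the right, 1 library per point. The whole WT library stands at 6632 CPM at 8 dpRA and 192750 CPM at 16 dpRA, and the 3 classes lie within 1.55-fold of one another in each library.

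In the sum over all kept cells, which mixes cell composition with expression, 0 genes rose and 2 fell of 18079 tested, Tmed6 (-7.29, SE 0.50) and the testis serine protease Prss21 (-6.47, SE 0.49), both with an edgeR adjusted p of 0.0494 and named after their values were seen. At an unadjusted p under 0.05 stood 3562 genes, and DESeq2 called 1955. Genes at least 1 log2 unit lower in each of the 4 pairs, which did not pass the test, included Abcc12 (91.1 CPM in WT and 5.08 CPM in SCARKO), Ldhal6b (483 and 20.2 CPM) and Fbp1 (468 and 18.0 CPM), besides Corin (5 and 0.540 CPM). Those at least 1 log2 unit higher included the defensin Defb36 (49.0 and 191 CPM), Sned1 (40.4 and 114 CPM) and the inhibin subunit gene Inhba (12.4 and 36.9 CPM). By camera with a preset correlation the energy metabolism (median -3.61), acrosome and spermatid (-3.63), piRNA pathway (-2.41), meiotic division (-1.71) and synaptonemal complex (-1.39) lists were lower, with adjusted p from 5.1e-08 to 0.00157 and an adjusted p of 0.503 for each with an estimated correlation. Without the 8 dpRA pair 3220 genes were called by edgeR, and without the 13 dpRA, 16 dpRA or 21 dpp pair 0 (2518, 1163 and 723 at an unadjusted p under 0.05).

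X-linked genes are silenced in pachytene spermatocytes, and the X share of UMIs on the X and the autosomes was lowest there. It was 0.185% in WT pachytene-diplotene cells at 16 dpRA (Wilson score 95% interval 0.182 to 0.188%) and 0.430% in WT at 21 dpp. At 13 dpRA it was 0.700% in WT (0.687 to 0.713%) and 0.814% in SCARKO (0.784 to 0.844%). Spermatid-like cells of WT stood at 2.25% at 16 dpRA. In early prophase cells the share was 2.49% ± 1.07 (SD, n = 4) in WT and 2.85% ± 0.933 (SD, n = 4) in SCARKO, higher in SCARKO in 4 of 4 pairs by 0.353 points (exact sign-flip permutation p = 0.125, the smallest possible, adjusted 0.2). It was also higher in 4 of 4 pairs in spermatogonia-like (by 0.163 points), Leydig-like (0.214 points) and mesenchymal-like cells (0.245 points) and in all kept cells (3.54% against 2.24%), with the same exact p. The WT cells of these classes also held more RNA of the 270 genes above at 13 dpRA, 16 dpRA and 21 dpp, and most of those genes were highest in X-poor late germ cells. The early prophase cells differed in their spread over clusters as well, and neither part of the X shifts was separated out. With at least 1000 genes per cell the Leydig-like share was higher in 3 pairs and lower in 1 (0.142 points, exact p = 0.25). The turned pair, 8 dpRA, then rested on 21 SCARKO and 57 WT cells, against 743 and 1225 at 500 genes, since the cluster of most others was left unnamed. In Sertoli-like cells it was 4.52% in SCARKO and 4.61% in WT over 3 pairs (exact p = 1), in endothelial-like cells 0.122 points higher over 3 pairs (exact p = 0.25), and in macrophage-like cells higher in 2 of 4 pairs (exact p = 0.5). No X share could pass 0.05 with this number of pairs.

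Among somatic cells, the shares of the classes differed in both directions between pairs. Lymphoid-like cells were lower in SCARKO in 4 of 4 pairs, 0.0940% ± 0.0257 (SD, n = 4) against 0.493% ± 0.492 (SD, n = 4), with an exact sign-flip permutation p of 0.125, the smallest possible, and 0.5 after adjustment over 8 classes. These shares rest on 1 to 24 cells per library, with 0.109% and 0.110% at 21 dpp, and with at least 300 genes per cell the class was lower in 3 pairs and higher in 1 (exact p = 0.375). Sertoli-like cells formed 10.8% ± 9.21 (SD, n = 4) of SCARKO and 7.46% ± 6.48 (SD, n = 4) of WT somatic cells (exact p = 0.625), and Leydig-like cells 49.1% ± 15.7 (SD, n = 4) and 55.3% ± 7.98 (SD, n = 4), higher in SCARKO in 3 pairs and lower in 1, 8 dpRA (-32.8 points; exact p = 1). With at least 1000 genes per cell or with doublets kept, where a cluster of most 8 dpRA Leydig-like cells was left unnamed, that pair differed by -7.42 and -12.5 points. Mesenchymal-like cells stood at 28.0% and 21.0% (exact p = 0.5). Macrophage-like (9.26% and 11.3%), endothelial-like (1.71% and 2.36%) and peritubular myoid-like cells (1.06% and 2.13%) were each lower in SCARKO in 3 of 4 pairs (exact p = 0.25 each). No cell was named erythroid-like in any library.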

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

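These differences were noticed after the values were seen, compare the 2 libraries of a time point, and were not tested. Sertoli-like cells made up a larger part of somatic cells in SCARKO than in WT at 8 dpRA (by 14.5 points) and 13 dpRA (by 1.72 points), and a smaller part at 21 dpp (-3.97 points). Leydig-like cells, which make testosterone, differed by -32.8 points at 8 dpRA and by 6.21 points at 13 dpRA. The gap at 8 dpRA depended on the naming of 1 cluster: it was -7.42 points with at least 1000 genes per cell and -12.5 points with doublets kept, where that cluster was left unnamed. Interstitial mesenchymal-like cells differed by 26.4 points at 8 dpRA, by -4.36 points at 13 dpRA and by 9.23 points at 21 dpp. The sign of each class thus changed between time points, and the shares rest on single libraries.

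The unnamed cluster of dividing cells, led by genes such as Mki67, held 1.80% of the SCARKO cells at 13 dpRA (exact 95% interval 1.42 to 2.25%) and 0.919% of the WT cells, and 2.39% and 0.812% at 21 dpp. The direction was opposite at 16 dpRA, with 0.603% in SCARKO and 1.58% in WT. The unnamed cluster led by long noncoding RNAs and Neat1, a nuclear RNA, held 1.15% of the SCARKO cells at 13 dpRA and 0.0459% of the WT cells (1 cell), and 1.63% and 0.131% (3 cells) at 16 dpRA. Neither cluster was assigned to a cell type, and these differences were untested.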

How the results depend on the processing

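The fits of genes at or above the library level and of the largest cluster of a class, the latter also with an estimated correlation for gene lists, and the removal of the 5% highest doublet scores, were chosen only after the results were seen. All other alternatives were fixed earlier. Of the settings tried, 232 left a main result the same, 86 moved it, 1 made it stronger and 2 reversed it. The 232 include settings for shares and X shares. Their paired sign-flip tests had too few pairs to pass the threshold under any setting. For shares and X shares, being counted as the same by that test is therefore no sign of stability. Counts below are genes called in SCARKO against WT by edgeR with Benjamini-Hochberg adjustment unless another tool is named, and the cause of a shift was not tested.

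In Sertoli-like cells 253 genes became 464 without the low-count filter, 74 with the DESeq2 Wald test, 92 in the largest cluster and 1 without the time block, with 54 to 476 on leaving out a pair. In spermatogonia-like cells 16 became 362 without the filter, 0 without the time block and 0 among genes at or above the library level, with a range of 0 to 470. In early prophase cells 3 became 194 without the filter and 6 with DESeq2. There it became 0 without the time block, with at least 1000 genes, without the highest doublet scores, in the largest cluster and among genes at or above the library level, with a range of 0 to 174.

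In Leydig-like cells 234 became 1217 without the filter, 479 with at least 1000 genes, 472 with doublets kept, 4 in the largest cluster, 0 without the time block and 0 among genes at or above the library level, with a range of 0 to 907. With at least 1000 genes or doublets kept, most Leydig-like cells at 8 dpRA lay in a cluster left unnamed. In the largest cluster only 17 of the 234 calls could be tested. In mesenchymal-like cells 114 became 616 without the filter, 0 without the time block and 10 among genes at or above the library level (45 to 557). In endothelial-like cells 0 became 12 without the filter (0 to 22). In macrophage-like cells 86 became 544 without the filter, 48 with at least 1000 genes, 0 without the time block and 0 among genes at or above the library level (35 to 286). Over all kept cells 2 became 1636 without the filter and 1955 with DESeq2. It became 0 with DESeq2 size factors, without the time block, with at least 1000 genes, with doublets kept and without the highest doublet scores (0 to 3220). The highest value of each range came without the 8 dpRA pair.

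With an estimated correlation 0 gene lists passed in any of the 8 fits: Sertoli-like (5 to 9 on leaving out a pair with the preset correlation), spermatogonia-like (5 to 8), early prophase (5 to 9), Leydig-like (8 to 11), mesenchymal-like (5 to 8), endothelial-like (1 to 2), macrophage-like (7 to 10) and all kept cells (9 to 12). With the preset correlation the largest cluster of a class gave 4 lists in early prophase, 0 in Leydig-like and 5 in macrophage-like cells, and with an estimated correlation 0 in each of the 7 classes fitted. The spermatid-like difference was -3.68 points with at least 1000 genes (exact p = 0.5).

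Without the 8 dpRA pair the difference in Sertoli-like share reversed to -0.41 points (range -0.41 to 5.74) and that in Leydig-like share to 2.78 points (-10.2 to 2.78). The lymphoid difference of -0.399 points was stronger by the unpaired exact permutation test (p = 0.0286; range -0.531 to -0.177). With at least 300 genes it had an exact p of 0.375 by the paired and 0.314 by the unpaired test, and with at least 1000 genes or Leiden resolution 0.5 no lymphoid class was named. The ranges were 15.3 to 31.1 points for spermatogonia-like, 13.2 to 23.2 for early prophase, -48.2 to -27.1 for pachytene-diplotene and -6.16 to -1.44 for spermatid-like cells, and -31.6 to -14 for germ cells among all cells. They were 0.443 to 10.7 for mesenchymal-like, -1.50 to -0.454 for myoid-like, -0.907 to -0.317 for endothelial-like and -2.99 to -0.820 for macrophage-like cells. The X share differed by 0.168 to 0.259 points in Leydig-like, 0.139 to 0.286 in mesenchymal-like, 0.00139 to 0.203 in macrophage-like, 0.0937 to 0.214 in spermatogonia-like and 0.291 to 0.429 in early prophase cells, and by 0.992 to 1.68 in all kept cells. With at least 1000 genes the Leydig-like difference was 0.142 points, in 3 of 4 pairs, with 21 and 57 cells left at 8 dpRA.

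Of the 168 named gene and class results 1 reversed, Cyp26b1 in the largest Leydig-like cluster (-0.27). Among their alternatives 1390 were the same, 436 weaker and 57 stronger. Without the time block 145 of 168 were weaker, against 1 of 168 with DESeq2 size factors.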

Other observations

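The tests of free RNA, of exchanged labels, of shared age and genotype and of regrouped libraries were chosen only after the results were seen. The tests of doublets, of separately set expression, of mixed Sertoli cells and of library batch were set down before their values were read, though for separately set expression the summed levels were already known.

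A set of 270 genes, most of them highest in late germ cells, fell in SCARKO in Leydig, mesenchymal, macrophage or spermatogonia-like cells. In WT at 16 dpRA their macrophage over Leydig log2 ratio had a median of 0.73 (quartiles 0.38 and 1.02, 261 genes), and 0.60 at 21 dpp. Both medians met the limit set for RNA freed from spermatocytes and spermatids. That limit was chosen after the values were seen. The summed levels of the 2 classes in WT at 16 dpRA already lay within 1.55-fold, so this could not decide for or against free RNA. Doublets with germ cells were excluded as the main source in Leydig-like cells, since the 5% of those cells richest in these UMIs held only 14.6% of them. Only 2.30% of the genes lay over 4-fold apart between macrophage and Leydig-like cells in WT at 16 dpRA, and 1.98% at 21 dpp. This met the limit set against expression set separately in each somatic type. The summed levels were already known to be close, however, and expression shared by both types would look the same. Expression in the somatic cells themselves was therefore not excluded. The doublet test covered Leydig-like cells only, and the other tests compared Leydig and macrophage-like cells. Doublets in macrophage-like cells, and all explanations in mesenchymal-like cells, stay open. So do those in spermatogonia-like cells, which stood at 15556 CPM against 5001 CPM in Leydig-like cells of WT at 8 dpRA.

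The fall of androgen-responsive genes such as Rhox5 in Sertoli-like cells was smaller at 13 dpRA than at 8 dpRA and 21 dpp. In the SCARKO library at 13 dpRA, 22 of 225 Sertoli-like cells had a Rhox5 UMI, and the 5 other genes stood 4.91 times as high in those cells as in the rest (95% interval 4.02 to 6.00, counting error only), against 1.31 to 1.84 times in the WT libraries. This is consistent with a mixture of Sertoli cells with and without androgen response, though the cells with Rhox5 also had more UMIs (median 4378 against 1354), and where they came from was not tested. Free RNA was excluded for Rhox5 by its Leydig over Sertoli ratio of 0.0432 (0.0267 to 0.0694). For the other androgen-responsive genes that ratio was not examined. Exchanged labels were excluded by a SCARKO over WT ratio of 0.275 (0.183 to 0.409).

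Leydig-like cells grouped by library. The excess of same-library neighbours among macrophage-like cells was 0.626 of that among Leydig-like cells, between the limits set for and against a library batch acting alike on all types, so this could not be told. Age and genotype of the animals could not be told from batch either, with 94.9% of SCARKO Leydig-like cells at 8 dpRA in the cluster shared with WT but no shared main cluster at the 3 other times. With 1 library per genotype and time, library, age and genotype cannot be parted.

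The libraries were also regrouped into every other split of equal size and the edgeR fit repeated. For Sertoli-like (real 253 calls, highest other 0, 1 split as large) and endothelial-like cells (real 0, highest other 3, 10 splits as large) only 10 splits were possible, too few to tell. Of 32 fitted splits, at least as many calls as the real one came from 4 in spermatogonia-like cells (real 16, highest other 535), 6 in early prophase cells (3 and 186), 4 in Leydig-like cells (234 and 458), 4 in mesenchymal-like cells (114 and 212) and 3 over all kept cells (2 and 8691), so chance was not excluded there. In macrophage-like cells only the real split, 1 of 32, reached its 86 calls (highest other 59), a share under 0.05 when all splits are counted. What drives the counts far above the real one was not tested.

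The splits differ in how far they keep the time pairs. Among the 8 splits that place the libraries of each time point in different groups, only the real one and the one that exchanges the 8 dpRA pair alone reached the real count in spermatogonia-like (277 calls), early prophase (109), Leydig-like (458) and mesenchymal-like cells (180). That split keeps genotype in 3 of the 4 pairs, so it is not unrelated to genotype. In macrophage-like cells only the real split of these 8 reached 86 calls (highest other 48), but 8 splits are too few for a share under 0.05, so chance stays open there too. Over all kept cells only the real split of the 8 made any calls (2), and the highest other was 0.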
